A study of Homo sapiens with 13 samples.

How the data were processed

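Expression was measured by RNA sequencing in 13 libraries: 6 from H1-derived mesenchyme (3 CD146++ and 3 CD146-) and 7 from sorted lipoaspirate cells (3 fresh and 2 cultured adventitial, 1 fresh and 1 cultured pericyte). Total RNA was amplified with a Nugen Ovation kit and sequenced in pairs of 100 bases. The primary cells came from 2 donors for 7 libraries, so some libraries share a donor. The labels do not tie libraries to donors, so donor could not be modelled, and p-values over these libraries may be too small.

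The values are RPKM as deposited by the authors, whose processing notes name alignment with STAR 2.3.0 to GRCh37 and assignment with HTSeq. The unit was read from the values, and whether reads or pairs were assigned, and the gene lengths used, are not stated. The analysis had been planned for counts. Since the values are RPKM, the count models were replaced by limma on log2(RPKM + 1), which had been written down as the fallback before the files were seen. On this scale the log2 difference of a gene with low values is understated.

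The table held 18505 genes in 13 columns, and all columns were matched to samples by the sample descriptions. Of these genes, 906 were at 0 in every library and 55 symbols had more than 1 entry. XIST and Y-linked genes, 13 in all, were left out, and 18492 genes were kept. By Ensembl identifier 97.4% of genes were matched to GENCODE 29, from which coordinates and lengths were taken. PECAM1 was not analysed here.

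Depth was estimated from the steps between low values. With 1 scale factor per library, 97.7% of 2575 low genes had values that were whole multiples of a step, against 0.1% with shuffled steps. The scale of the estimate rests on annotated exon lengths. Per library, 9725 to 10785 genes were at 1 RPKM or more, and the fresh primary libraries had the lowest depth, so their low values are the least precise.

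There were 7 comparisons. Each used limma 3.58.1 with a trend and robust empirical Bayes, two-sided, on genes with at least 1 RPKM in at least as many libraries as the smaller group holds, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. Comparisons within primary cells had a term for culture state or population. The interaction was fitted to all 13 libraries with a mean per group. Each pericyte group held 1 library, so the spread in that fit came from the stem cell-derived and adventitial libraries alone. The p-values measure spread between these samples, not between donors or differentiations in general. Adjusted p values of limma and camera rest on a model, and with 3 against 3 libraries there are 10 ways to regroup, and 4 that part the pairs described next, too few for an exact test to reach 0.05.

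Replicate numbers are shared by the CD146++ and CD146- libraries. After removal of group means, the correlations of libraries with the same number were 0.112, 0.535 and 0.641, all above 0.1, which by the rule fixed beforehand pairs these samples. CD146++ replicate 2 also had a correlation of 0.279 with CD146- replicate 1, and the labels do not say that a number marks 1 differentiation. The pairing thus rests on the values. CD146++ replicate 2 and CD146- replicate 3 also lay between the fractions. Correlations that come from this were not separated from those of a shared differentiation. Single genes are given from the fit without a block, and counts and list tests with the replicate number as a block stand beside the comparison.

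Gene lists, 30 in all, were written before the files were seen. They were tested with camera at an inter-gene correlation of 0.01 where at least 5 members were tested, in 185 tests, with adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Members called with adjustment over the list alone are given too. In the text, rose and fell are used only for genes past the threshold.

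Genes were named by a rule fixed beforehand: the sort markers, the 6 genes (5 in the later comparisons) with the largest log2 difference in each direction among those past the threshold, with a mean of at least 10 RPKM in the higher group and no overlap between groups, and up to 4 members per described list. For the interaction, overlap was not considered. Clone names and pseudogenes were passed over among the largest differences, by the form of the symbol. That filter also passed over SFRP1, IGFBP6 and MFAP5, which are given only as list members. Some of their differences exceed those of genes named by size. Where fewer than 2 members of a list passed, the 2 with the highest mean were taken. No fold is given for a gene listed at 0 in the whole of the other group. Some results that the rule names are not reported here. The levels of ADIPOQ and PLIN4 in the pericyte libraries, of DLK1 and FREM1 in CD146++ replicate 2, and the genes named as shared or in the closing paragraphs on HOX genes were chosen after their values were seen.

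The pipeline was tested on simulated data with 200 changed genes per comparison. For a log2 change of 2 it recovered 95.5% in the CD146++ against CD146- comparison, 44.8% in the pericyte comparison, 71.6% for culture, 26.9% and 62.7% in the source comparisons, 82.1% in the interaction and 0% for aldehyde dehydrogenase activity. The simulated errors were independent between genes, unlike those of real libraries, so these shares need not hold for the data. No pair of libraries in a group had identical values. Libraries of unlike depth would differ in this even for the same RNA, so duplication is not excluded.

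Alternatives written before the files were seen were other filters, thresholds, covariates, sample sets, blocks, list tests and each library left out. Added after the data were examined were pseudocounts of 0.1 and 10, median-ratio and quantile scaling, voom on approximate reads, scaling in the list counts, the block in the list tests, and fry and the block for the set of pericyte genes. R 4.3.3, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.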

Results

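RNA was sequenced from 13 libraries of human mesenchymal and perivascular cells. There were 6 libraries from mesenchyme derived from H1, a human embryonic stem cell line, by way of a mesodermal progenitor. Of these, 3 came from cells sorted as CD146++ with bright CD73 and dim CD140, and 3 from CD146- cells with CD140. Their labels give a progenitor sort at day 3.5, growth factors at 10 ng/mL, the compound SB431542 at 10 uM and harvest at day 14 to 18. The day of each library is not given. The other 7 came from cells of human lipoaspirate, the fat removed by liposuction, which were either pelleted after sorting (fresh) or grown for 3 passages (cultured). The cultured primary cells were grown with 20% FBS. Adventitial cells (CD34+ and CD146-) gave 3 fresh libraries (not split by aldehyde dehydrogenase activity, bright, and dim) and 2 cultured ones (bright and dim), and pericytes (CD34- and CD146+) gave 1 fresh and 1 cultured library. Estimated depth was 8070000 to 11500000 reads in the stem cell-derived libraries, 3470000 to 5010000 in the cultured primary ones and 1830000 to 2450000 in the fresh ones.

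On the first principal component, with 50.2% of the variance, the fresh primary libraries lay apart from the stem cell-derived ones, and the cultured primary libraries lay between them. Transcripts of the 13 mitochondrial genes made up 11.6% to 26.7% of the RPKM total in all libraries but that of fresh pericytes, where they made up 35.6%. The plot of principal components shows each library.

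**Figure D1:**
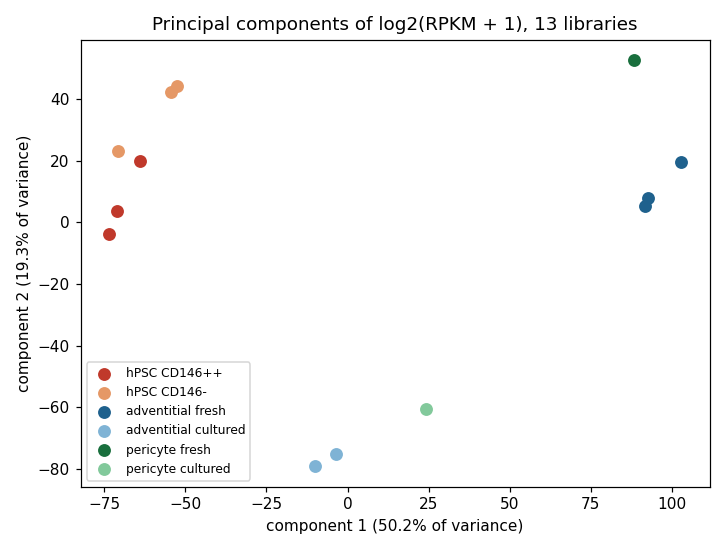
Each point is 1 of the 13 libraries, placed by the first 2 principal components of log2(RPKM + 1), with the share of variance on each axis and a colour for each of the 6 groups. The 4 fresh primary libraries lie on the right between 88.3 and 102.71 on component 1, and the 6 stem cell-derived libraries on the left between -73.5 and -52.5.

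The first comparison asked how the CD146++ fraction of the stem cell-derived mesenchyme differed from the CD146- fraction. The CD146++ cells had more MCAM, the gene of CD146, at 9.37 ± 4.03 RPKM against 0.758 ± 0.595 (SD, n = 3 in each fraction), a log2 difference of 2.52 ± 0.36 (SE). NT5E, the gene of CD73, was at 128 ± 60.3 against 9.02 ± 3.81 RPKM, a difference of 3.63 ± 0.45 (adjusted p = 0.0118, and 0.0146 for MCAM). Both genes encode antigens of the sort, so their difference describes the gate. PDGFRA, which encodes a CD140 antigen, was at 26.7 ± 19.9 against 116 ± 40.2 RPKM. It did not pass the limma test without the replicate block (log2 difference -2.30 ± 0.53, adjusted p = 0.0503), and PDGFRB had a log2 difference of -0.10 ± 0.39. MCAM (ENSG00000076706) lies on chromosome 11 from 119308529 to 119321521 on the minus strand. NT5E (ENSG00000135318) lies on chromosome 6 from 85449584 to 85495791 and PDGFRA (ENSG00000134853) on chromosome 4 from 54229097 to 54298247, both on the plus strand. Positions are those of GENCODE 29 in GRCh38, which differs from the GRCh37 of the submitters' processing notes.

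**Figure D2:**
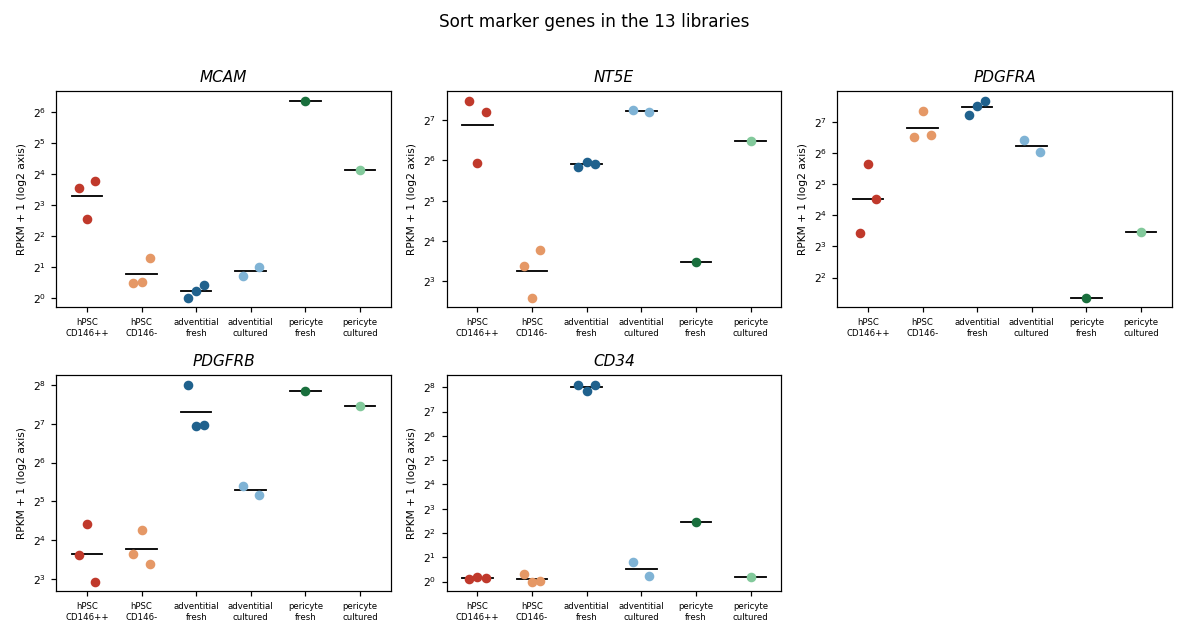
Each point is the RPKM + 1 of a sort marker gene in 1 of the 13 libraries on a log2 axis, by group, and the line is the mean on the log scale. MCAM was between 4.84 and 12.6 RPKM in the CD146++ libraries, and at 81.0 and 16.6 RPKM in the fresh and cultured pericyte libraries.

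Among the genes with the largest differences, the CD146++ cells had more G0S2, an inhibitor of lipolysis (96.6 ± 95.4 against 0.582 ± 0.494 RPKM, log2 difference 5.24 ± 0.91). They also had more of the receptor gene ELTD1 (3.81 ± 0.57), STMN2, a regulator of microtubules (98.7 ± 29.2 against 6.14 ± 1.10 RPKM, 3.77 ± 0.23), ANKRD1 (3.52 ± 0.50) and CHRDL1, an antagonist of bone morphogenetic proteins (3.34 ± 0.23). The CD146- cells had more COL14A1 (237 ± 144 against 10.7 ± 14.6 RPKM, -4.90 ± 0.97), DLK1, a regulator of adipocyte differentiation (328 ± 216 against 19.8 ± 20.7 RPKM, -4.21 ± 0.74). Also higher in them were the growth factor genes HGF (-3.90 ± 0.51) and IGF2 (-3.88 ± 0.81), COLEC11 (-3.65 ± 0.77) and the matrix gene FREM1 (-3.58 ± 0.76). As the rule that named them required, each of these lay on 1 side in all 6 libraries, with adjusted p between 0.00253 and 0.0397. CD146++ replicate 2 lay nearest to the CD146- libraries for DLK1, with 43.8 RPKM, and for FREM1, with 44.0 RPKM.

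**Figure D3:**
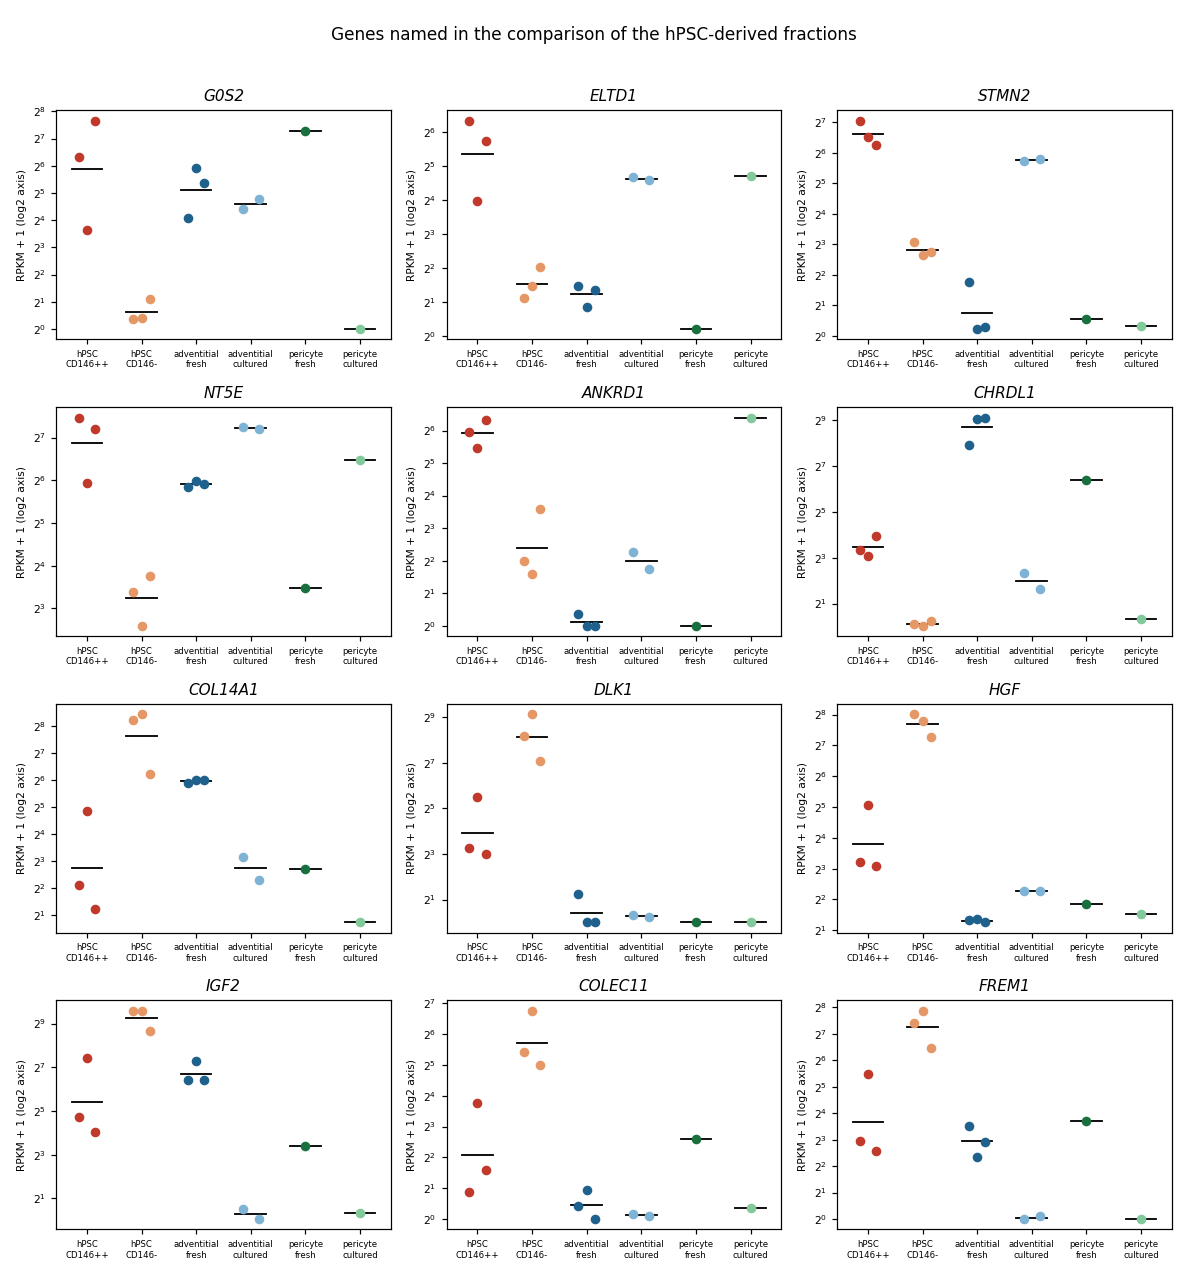
Each point is the RPKM + 1 of a gene in 1 of the 13 libraries on a log2 axis, by group, and the line is the mean on the log scale. In the stem cell-derived libraries, the first 6 genes were higher in every CD146++ library (STMN2 74.8 to 131 RPKM) than in every CD146- library (5.30 to 7.39), and the last 6 were lower. This lack of overlap was part of the rule that named the genes.

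Of the 23 tested mural and pericyte genes, 7 rose in the CD146++ cells and 0 fell (8 and 1 adjusted over the list alone). Those that rose included the contractile genes TAGLN (1.71 ± 0.33), MYLK (1.49 ± 0.21) and MYL9 (1.35 ± 0.22) beside MCAM, and the list as a whole did not pass (camera adjusted p = 0.354). Of 13 matrix collagens, 4 fell and 1 rose (10 and 2 adjusted over the list alone). COL14A1, COL6A3 (-2.88 ± 0.61), COL6A2 (-2.37 ± 0.44) and COL6A1 (-1.89 ± 0.40) fell, with a camera adjusted p = 0.00424 and an adjusted p = 0.681 with an estimated correlation. Of 21 adventitial and fibroblast genes, ABCA8 fell (-3.22 ± 0.57) and 4 rose, among them IGFBP6 (2.12 ± 0.23), SFRP2 (1.85 ± 0.36) and CLU (1.33 ± 0.14). Adjusted over the list alone, 5 rose and 10 fell, and the list did not pass (adjusted p = 0.0656). With the replicate number as a block it did (camera adjusted p = 0.0139, adjusted p = 0.643 with an estimated correlation). Of 19 haematopoietic niche factors, 3 fell and 2 rose (4 and 6 adjusted over the list alone). CXCL12, the chemokine that retains blood stem cells in the marrow, fell (-2.49 ± 0.35, 4.65 ± 2.19 against 30.1 ± 9.18 RPKM), as did ANGPTL1 (-2.13 ± 0.48) and ANGPT1 (-1.37 ± 0.24), and IGFBP2 rose (1.95 ± 0.36). The median of that list was -0.099 and its mean 0.114 (camera adjusted p = 0.829).

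Of 18 tested HOX genes, which encode positional transcription factors, 5 fell and 0 rose (5 and 0 adjusted over the list alone). They included HOXA13 (-2.23 ± 0.40), HOXA10 (-2.09 ± 0.30), HOXB13 (-1.89 ± 0.30) and HOXA11 (-1.76 ± 0.15); the list had a camera adjusted p = 0.00424 and an adjusted p = 0.681 with an estimated correlation. Of 15 fetal and oncofetal genes, 4 fell and 2 rose (6 and 2 adjusted over the list alone). DLK1, IGF2 and PLAGL1 (-1.58 ± 0.29) fell and HMGA1 rose (2.11 ± 0.42), with a camera adjusted p = 0.0432 and an adjusted p = 0.681 with an estimated correlation. Of 4 tested epithelial genes, the keratin genes KRT8 (2.16 ± 0.43), KRT18 (1.99 ± 0.37) and KRT7 (1.80 ± 0.19) rose (4 adjusted over the list alone). Of 22 Wnt pathway genes, 5 rose and 5 fell (7 and 10 adjusted over the list alone, camera adjusted p = 0.193). The secreted antagonist SFRP1 was at 385 ± 249 against 12.6 ± 6.04 RPKM (4.65 ± 0.64), DKK3 also rose (1.96 ± 0.25), and FRZB (-2.15 ± 0.46) and WNT11 (-1.91 ± 0.42) fell.

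Of 23 genes of TGF-beta and YAP response, 4 rose and 0 fell (7 and 3 adjusted over the list alone, camera adjusted p = 0.384): ANKRD1, INHBA (2.12 ± 0.33), TAGLN and AMOTL2 (0.85 ± 0.12). Of 23 glycolysis and hypoxia genes, PFKP (1.85 ± 0.34), SLC2A1 (1.42 ± 0.18) and NDRG1 (0.76 ± 0.17) rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 0.0167, adjusted p = 0.681 with an estimated correlation). Of 8 bone and cartilage genes, HAPLN1 (1.53 ± 0.28) and MATN3 (1.28 ± 0.20) rose and 0 fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0929). No member of the 30 cell cycle genes passed (0 adjusted over the list alone), although their median log2 difference was 0.71 and the list passed camera (adjusted p = 0.000149, adjusted p = 0.681 with an estimated correlation). TOP2A was at 120 ± 30.7 against 79.8 ± 43.0 RPKM and RRM2 at 124 ± 35.5 against 66.9 ± 42.2.

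In all, 659 of 10735 tested genes passed an adjusted p of 0.05 with limma, 434 higher and 225 lower in the CD146++ cells. With the replicate number as a block, 2242 genes passed, among them all 659, and with the block 11 gene lists passed camera in place of 9, the adventitial and the basement membrane list (adjusted p = 0.0395) being those added. The basement membrane list had an adjusted p = 0.643 with an estimated correlation. The count was 13 without CD146++ replicate 1, 42 without CD146++ replicate 3, 36 without CD146- replicate 1, 72 without CD146- replicate 2, 1032 without CD146++ replicate 2 and 1805 without CD146- replicate 3. Whichever library was left out, 5 of the 47 genes named for this comparison that passed (CHRDL1, STMN2, HOXA11, KRT7 and CLU) stayed past the threshold.

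The next comparison set primary pericytes against adventitial cells, with culture state in the model. The pericyte libraries had far more NDUFA4L2, a nuclear gene used as a pericyte marker (125 ± 18.8 RPKM, SD, n = 2, against 0.245 ± 0.278, n = 5, log2 difference 6.66 ± 0.30). Also higher were the receptor gene GPR116 (6.48 ± 0.44), the small heat shock protein gene HSPB7 (5.10 ± 1.01), TINAGL1 (5.07 ± 0.25), NOTCH3, a receptor of mural cells (4.87 ± 0.55), and ACTA2, smooth muscle actin (97.9 RPKM fresh and 854 RPKM cultured, 4.82 ± 0.52). They had less of the matrix genes FBLN1 (-5.23 ± 0.43) and DCN (18.1 ± 14.0 against 849 ± 642 RPKM, -4.75 ± 0.47), of AADAC (-4.73 ± 0.68), PTGIS, prostacyclin synthase (-4.72 ± 0.44), and PI16 (-4.67 ± 0.57). PYURF was listed at 0 in both pericyte libraries and averaged 30.4 ± 13.2 RPKM in the adventitial ones. Adjusted p for these genes ranged from 0.000222 to 0.0289.

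Of the sort markers, MCAM was higher in pericytes (4.80 ± 0.58, adjusted p = 0.00592) and PDGFRA lower (-4.54 ± 0.66, adjusted p = 0.0117). NT5E was lower (-1.64 ± 0.39, adjusted p = 0.0475). CD34, at 4.53 RPKM in fresh and 0.141 RPKM in cultured pericytes against 227 to 272 RPKM in fresh and at most 0.731 RPKM in cultured adventitial cells, did not pass (-3.08 ± 0.96, adjusted p = 0.0892), nor did PDGFRB (1.32 ± 0.48, adjusted p = 0.122) or PTPRC, the gene of the blood cell antigen CD45 (0.29 ± 0.35). PTPRC stayed at or under 1.43 RPKM in every library.

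Of 29 mural and pericyte genes, 12 rose in pericytes and 1 fell (21 and 1 adjusted over the list alone, camera adjusted p = 1.31e-14, adjusted p = 0.0615 with an estimated correlation). Of 32 adventitial and fibroblast genes, 15 fell and 0 rose (25 and 0 adjusted over the list alone), MFAP5 by 4.68 ± 0.43 among them, with a camera adjusted p = 3.44e-13 and an adjusted p = 0.486 with an estimated correlation. Of 21 Notch pathway genes, NOTCH3, NOTCH1 (2.86 ± 0.51), HEYL (2.43 ± 0.39) and MAML2 (1.49 ± 0.35) rose and 0 fell (6 and 1 adjusted over the list alone, camera adjusted p = 0.0150, adjusted p = 0.486 with an estimated correlation). Of 14 basement membrane genes, 5 rose, with COL4A1 (2.57 ± 0.60), COL4A2 (2.51 ± 0.61) and LAMA5 (2.09 ± 0.36) among them, and LAMA2 fell (-4.09 ± 0.46). With median-ratio scaling 3 rose. That list gave 6 and 1 adjusted over the list alone, a camera adjusted p = 0.0137 and an adjusted p = 0.486 with an estimated correlation. Of 14 bone and cartilage genes, SOX9 (-3.28 ± 0.49), OGN (-3.28 ± 0.80) and MSX1 (-2.90 ± 0.46) fell and 0 rose (6 and 0 adjusted over the list alone, camera adjusted p = 0.0150, adjusted p = 0.517 with an estimated correlation).

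Of 15 adipocyte genes, the lipase gene PNPLA2 (4.40 ± 0.81), CD36 (3.32 ± 0.41) and FABP4 (2.46 ± 0.45) rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.95e-05, adjusted p = 0.682 with an estimated correlation). The fresh pericyte library held 1600 RPKM of ADIPOQ, the adiponectin gene, 626 RPKM of PNPLA2, 603 RPKM of FABP4 and 322 RPKM of PLIN4, against 0, 26.7, 3.67 and 0.375 RPKM in the cultured pericyte library, and the highest ADIPOQ value among adventitial libraries was 8.40 RPKM. Of 31 cytosolic ribosomal protein genes, 17 fell and 0 rose (30 and 0 adjusted over the list alone, median -1.89; 8 fell with median-ratio and 15 with quantile scaling). Among these were RPL11 (-2.97 ± 0.66), RPS18 (-2.97 ± 0.67), RPS3 (-2.81 ± 0.64) and RPSA (-2.73 ± 0.47), with a camera adjusted p = 3.44e-13 and an adjusted p = 0.486 with an estimated correlation. Short genes as a whole were lower in the pericyte libraries: the median log2 difference was -0.56 in the tenth of genes with the shortest coding length and 0.18 in the longest.

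In all, 883 of 11914 tested genes passed, 308 of them higher in pericytes and the others lower. The median difference over all genes was -0.112, and median-ratio scaling, which moved it to 0.001, gave 49.7% of 813 calls higher in place of 34.9%. The count was 172, 179 and 2124 without the fresh ALDH bright, ALDH dim and unfractionated adventitial library, 253 and 295 without the cultured bright and dim library, 2006 without the cultured pericyte library and 56 with no culture term. Without the fresh pericyte library it was 793, of which 273 were among the 883. Of the 33 named genes that passed, 17 were lost without some library, NT5E, HSPB7, NOTCH1, COL4A1, PNPLA2, FABP4, SOX9 and RPL11 among them.

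Cultured primary cells were then set against fresh ones, with population in the model. Culture brought much higher levels of GREM1, an antagonist of bone morphogenetic proteins (886 ± 732 RPKM, SD, n = 3, against 3.85 ± 1.89, n = 4, log2 difference 7.16 ± 0.37). It also brought more SCUBE3 (6.29 ± 0.36), KIAA1199 (5.73 ± 0.29) and TGFBI, an extracellular matrix gene (352 ± 107 against 5.56 ± 1.95 RPKM, 5.72 ± 0.31). APOD, an apolipoprotein gene that averaged 11300 ± 10900 RPKM in the fresh libraries, was at 7.13 ± 4.05 after culture (-9.03 ± 0.82). CXCL14 (-8.62 ± 0.93), the alcohol dehydrogenase gene ADH1B (-7.80 ± 0.33), PDK4 (-7.51 ± 0.30) and DPT (-7.16 ± 0.38) fell too. CD34 fell from 194 ± 128 to 0.345 ± 0.334 RPKM (-5.96 ± 0.88), PDGFRB fell (-1.53 ± 0.43) and NT5E rose (1.82 ± 0.36), while PDGFRA did not pass (-0.26 ± 0.60). Adjusted p for the genes that passed ranged from 4.40e-05 to 0.0310.

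Of 26 tested cell cycle genes, 24 rose and 0 fell (25 and 0 adjusted over the list alone). Among these were RRM2 (4.50 ± 0.56), TPX2 (4.43 ± 0.62), CCNA2 (4.35 ± 0.40) and TOP2A (4.24 ± 0.63), with a camera adjusted p = 3.38e-11 and an adjusted p = 0.366 with an estimated correlation. Of 25 immediate early and heat shock genes, 20 fell and 1 rose (20 and 1 adjusted over the list alone). Among these were FOSB (999 ± 285 to 13.1 ± 5.10 RPKM, -6.14 ± 0.39), ZFP36 (-5.54 ± 0.31), BTG2 (-5.36 ± 0.42) and JUNB (-5.32 ± 0.29) (camera adjusted p = 1.87e-11, adjusted p = 0.360 with an estimated correlation). Of 32 adventitial and fibroblast genes, 23 fell and 1 rose (24 and 1 adjusted over the list alone), with APOD, CXCL14, the complement genes C3 (-6.87 ± 0.78) and CFD (-6.32 ± 0.81) among those that fell (camera adjusted p = 7.82e-10, adjusted p = 0.366 with an estimated correlation). Of 17 cytokines and chemokines, 11 fell and 2 rose (12 and 2 adjusted over the list alone). NFKBIA (-4.58 ± 0.43), CXCL9 (-4.09 ± 0.31) and CXCL2 (-3.94 ± 0.35) fell and PTX3 rose (19.4 ± 13.9 to 833 ± 356 RPKM), with a camera adjusted p = 9.39e-05 and an adjusted p = 0.366 with an estimated correlation.

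Of 24 glycolysis and hypoxia genes, 15 rose and 0 fell (16 and 2 adjusted over the list alone). Among these were PKM (3.03 ± 0.34), GAPDH (2.99 ± 0.45), PFKP (2.92 ± 0.34) and PGAM1 (2.85 ± 0.38) (camera adjusted p = 0.000606, adjusted p = 0.366 with an estimated correlation). Of 24 TGF-beta and YAP response genes, 9 rose and 1 fell (10 and 2 adjusted over the list alone), with INHBA (5.57 ± 0.54) and ANKRD1 (3.21 ± 0.78) beside TGFBI. ANKRD1 was at 29.9 ± 46.5 RPKM after culture (camera adjusted p = 0.0232, adjusted p = 0.366 with an estimated correlation). Of 24 niche factors, 14 fell and 4 rose (14 and 6 adjusted over the list alone), the insulin-like growth factor gene IGF1 (-6.14 ± 0.48), ANGPTL2 (-3.63 ± 0.41), BMP4 (-3.56 ± 0.29) and ANGPTL1 (-3.46 ± 0.27) among those that fell (camera adjusted p = 0.000937, adjusted p = 0.366 with an estimated correlation). Of 13 blood cell genes, 9 fell and 0 rose (12 and 0 adjusted over the list alone). LYZ averaged 39.4 ± 38.0 RPKM and CD74 46.1 ± 29.7 in the fresh libraries against 0.0606 ± 0.105 and 0.761 ± 0.636 after culture, and HBA2 was listed at 0 in the 3 cultured libraries (camera adjusted p = 1.76e-05, adjusted p = 0.366 with an estimated correlation). Of 13 mitochondrial transcripts, 7 fell and 0 rose (8 and 0 adjusted over the list alone, and 4 fell with quantile scaling, where the median was -0.598 in place of -1.388). Among these were MT-ND1 (-2.29 ± 0.44) and MT-ND2 (-2.03 ± 0.49) (camera adjusted p = 0.00108, adjusted p = 0.446 with an estimated correlation).

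In all, 3553 of 11095 genes passed, 1989 higher and 1564 lower after culture. The median difference over all genes was 0.131, and -0.032 with median-ratio scaling, which gave 46.1% of 3542 calls higher in place of 56.0%. The count was 1457 and 1310 without the cultured ALDH bright and dim library (46.4% and 46.7% of them higher) and 1935 with no population term, and 41 of the 45 named genes that passed stayed past the threshold whichever library was left out.

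Both sources of CD146-positive cells were compared next, which also compares a cell line with donor tissue and a differentiation protocol with sorting or passage. The stem cell-derived CD146++ cells had COLEC10 at 96.6 ± 38.6 RPKM (SD, n = 3) against 0.0880 ± 0.124 in pericytes (n = 2, log2 difference 6.40 ± 0.44), and more ABRACL (6.19 ± 0.50), STMN2 (6.17 ± 0.32) and KRT18 (5.68 ± 0.96). KDR, a receptor for vascular endothelial growth factor, was at 94.0 ± 45.6 RPKM in them and listed at 0 in both pericyte libraries. They had less HSPB7 (0.186 ± 0.164 against 368 ± 14.0 RPKM, -8.29 ± 0.24), CD36 (-7.39 ± 0.50), the small heat shock protein gene CRYAB (-6.95 ± 0.26), NDUFA4L2 (-6.94 ± 0.24) and GPX3 (-6.80 ± 0.83). PDGFRB, the receptor on which pericyte recruitment depends, was at 12.8 ± 7.03 against 202 ± 36.9 RPKM (-4.00 ± 0.49, adjusted p = 0.00849), and MCAM did not pass (-1.96 ± 0.75, adjusted p = 0.101).

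Of 27 mural and pericyte genes, 12 were lower in the stem cell-derived cells and 0 higher (13 and 0 adjusted over the list alone). Among these were NOTCH3 (-5.76 ± 0.54), ACTA2 (-4.50 ± 1.00) and CSPG4 (-4.22 ± 0.24) (camera adjusted p = 7.95e-12, adjusted p = 0.103 with an estimated correlation). Of 13 collagens, 6 were lower and 0 higher (6 and 0 adjusted over the list alone), with COL15A1 (-4.99 ± 0.93) and COL6A2 (-4.89 ± 0.57) among them (camera adjusted p = 0.000580, adjusted p = 0.357 with an estimated correlation). Higher in the stem cell-derived cells were 26 of 30 cell cycle genes (29 adjusted over the list alone, camera adjusted p = 1.78e-08), 30 of 31 ribosomal protein genes (31, 5.57e-09), 23 of 29 oxidative phosphorylation genes (23, 4.84e-05), 4 of 5 tested pluripotency genes (4, 0.00782) and 3 of 6 tested epithelial genes (4, 0.0328), with 0 lower in each. The pluripotency list has 18 genes, and its other members were not tested here. With median-ratio scaling, 6 of the oxidative phosphorylation genes and 20 of the ribosomal protein genes were higher (8 and 26 with quantile scaling), and 23 of the cell cycle genes. Short genes as a whole were higher here, by a median of 0.88 in the tenth with the shortest coding length. Each of these lists had an adjusted p = 0.357 with an estimated correlation. Among them were RRM2 (4.75 ± 0.74), RPSA (4.12 ± 0.37), ATP5A1 (2.59 ± 0.30), KRT19 (5.68 ± 0.37), KRT8 (5.65 ± 0.25) and DPPA4 (3.00 ± 0.28), and the RNA-binding protein genes LIN28B (39.5 ± 13.6 RPKM) and LIN28A (13.7 ± 3.29), both listed at 0 in the pericyte libraries.

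In all, 3583 of 11304 genes passed, 2767 higher and 816 lower in the stem cell-derived cells. The median difference over all genes was 0.442, and median-ratio scaling, which moved it to 0.055, gave 53.2% of 2621 calls higher in place of 77.2%. With limma, 0 genes passed without CD146++ replicate 3 (3528 at an unadjusted p under 0.05), 10 without replicate 1, 1106 without replicate 2, 6306 without the fresh pericyte library and 6847 without the cultured one. Each of the 40 named genes that passed was lost without at least 1 library.

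The CD146- cells of both sources were compared in the same way. The stem cell-derived cells had DLK1 at 328 ± 216 RPKM (SD, n = 3) against 0.358 ± 0.559 in adventitial cells (n = 5, log2 difference 7.77 ± 0.47), COLEC10 at 185 ± 74.1 (7.42 ± 0.28) and KDR at 206 ± 33.4 (7.32 ± 0.27). PROK1 (79.3 ± 39.6 RPKM) and LIN28B (70.9 ± 2.84 RPKM) were listed at 0 in the 5 adventitial libraries. Lower were APOD (-9.45 ± 2.84), CFD, also called adipsin (-7.20 ± 2.12), the matrix protein gene MGP (-7.14 ± 1.90), NUPR1 (-6.71 ± 0.28) and PRG4, the gene of lubricin (-6.62 ± 0.79). NT5E (-3.18 ± 0.46) and PDGFRB (-2.73 ± 0.65) were lower, PDGFRA was not called (-0.16 ± 0.45), and CD34 did not pass (-4.89 ± 2.06). Adjusted p for the genes called here ranged from 6.30e-07 to 0.0383.

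Of 32 adventitial and fibroblast genes, 17 were lower and 1 higher (19 and 1 adjusted over the list alone). Among these were MFAP5 (-8.02 ± 0.53) and GPX3 (-6.48 ± 1.21) (camera adjusted p = 3.49e-10, adjusted p = 0.476 with an estimated correlation). Of 16 fetal and oncofetal genes, 10 were higher and 1 lower (11 and 1 adjusted over the list alone), with IGF2BP1 (5.30 ± 0.20) and MEST (4.70 ± 0.58) beside DLK1 and LIN28B (camera adjusted p = 0.000426, adjusted p = 0.131 with an estimated correlation). Of the 18 pluripotency genes in the list, 4 were tested, and these were higher (4 adjusted over the list alone), DNMT3B (1.54 ± 0.27), LIN28A and DPPA4 beside LIN28B. The others, POU5F1, NANOG and SOX2 among them, were under the filter or absent from the data. Of 8 endothelial genes, KDR, FLT1 (4.14 ± 0.33) and TEK (3.90 ± 0.44) were higher and 0 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.247). Of 20 interferon response genes, 6 were lower and 0 higher (6 and 0 adjusted over the list alone). Among these were IFI27 (-3.32 ± 0.21), XAF1 (-2.54 ± 0.46) and OAS2 (-1.58 ± 0.30) (camera adjusted p = 0.000625, adjusted p = 0.476 with an estimated correlation). Of 13 adipocyte genes, CD36 (-4.46 ± 0.21), G0S2 (-4.29 ± 0.42) and PNPLA2 (-1.43 ± 0.37) were lower and 0 higher (3 and 0 adjusted over the list alone, camera adjusted p = 2.61e-05, adjusted p = 0.476 with an estimated correlation).

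In all, 3197 of 11492 genes passed, 2108 higher and 1089 lower in the stem cell-derived CD146- cells. The median difference was 0.254, and median-ratio scaling, which moved it to 0.012, gave 50.6% of 2645 calls higher in place of 65.9%. The count was 1049, 1066 and 1325 without CD146- replicate 1, 2 and 3, and 23 of the 28 named genes that passed stayed past the threshold whichever library was left out. APOD, CFD, MGP, PDGFRB and PNPLA2 did not; mean APOD was 15000 RPKM in the fresh and 9.47 RPKM in the cultured adventitial libraries, CFD 1380 and 5.49 RPKM, and MGP 1240 and 9.25 RPKM.

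Whether the CD146 difference itself differed between sources was tested by an interaction. Fresh and cultured pericytes were 1 library each in it, so its SE and adjusted p hold no spread between pericyte libraries. Where 1 pericyte library was left out, the other was set against the mean of fresh and cultured adventitial cells. Such a fit mixes culture state with population. Compared with the contrast in primary cells, that in the stem cell-derived cells was more positive for S100A16 (6.61 ± 0.36), STMN2 (6.61 ± 0.53), G0S2 (6.47 ± 1.18), THBD, the gene of thrombomodulin (6.18 ± 0.66), and CD9 (5.55 ± 0.45). It was more negative for NDUFA4L2 (-6.74 ± 0.28), GPR116 (-6.17 ± 0.32), ACTA2 (-5.56 ± 0.54), HSPB7 (-5.14 ± 0.35) and TINAGL1 (-5.00 ± 0.19). ACTA2 was at 13.2 ± 7.55 RPKM in the CD146++ and 20.5 ± 7.78 in the CD146- cells (SD, n = 3 each). The gates were unlike, with CD73 gated only in the stem cell-derived and CD34 only in the primary cells, which bears on NT5E and CD34. Of the sort markers, MCAM (-2.20 ± 0.46), PDGFRA (2.14 ± 0.66), NT5E (5.21 ± 0.55) and CD34 (2.96 ± 0.26) passed, and PDGFRB did not (-1.47 ± 0.57). Adjusted p for those that passed ranged from 5.29e-07 to 0.0318.

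Of 31 mural and pericyte genes, 18 had a more negative contrast in the stem cell-derived cells and 1 a more positive one (22 and 1 adjusted over the list alone). Among these were NOTCH3 (-4.72 ± 0.66) and PLN (-3.65 ± 0.55) (camera adjusted p = 1.11e-11, and 0.00818 with an estimated correlation). Of 32 adventitial and fibroblast genes, 23 were more positive and 1 more negative (23 and 1 adjusted over the list alone). Among these were IGFBP6 (6.13 ± 0.54), SFRP2 (5.54 ± 0.54) and FBLN1 (4.81 ± 0.39) (camera adjusted p = 1.26e-07, adjusted p = 0.308 with an estimated correlation). Of 15 adipocyte genes, 10 were more negative and 1, G0S2, more positive (11 and 1 adjusted over the list alone, camera adjusted p = 1.51e-07, and 0.00818 with an estimated correlation). PNPLA2 (-4.11 ± 0.45) and PLIN4 (-3.90 ± 0.28) were among the more negative ones. ADIPOQ turned from -3.93 ± 0.55 to 1.39 without the fresh pericyte library described above. There, cultured pericytes alone were set against the mean of fresh and cultured adventitial cells. Of 16 bone and cartilage genes, 8 were more positive and 2 more negative (10 and 2 adjusted over the list alone). Among these was SOX9 (4.28 ± 0.37; camera adjusted p = 0.00579, adjusted p = 0.121 with an estimated correlation). Of 31 ribosomal protein genes, 29 were more positive and 0 more negative (30 and 0 adjusted over the list alone). Among these was RPSA (3.11 ± 0.49; camera adjusted p = 1.81e-09, adjusted p = 0.505 with an estimated correlation). Short genes as a whole were more positive too, with a median of 0.72 in the tenth with the shortest coding length and -0.22 in the longest, and ribosomal protein transcripts made up 0.96% and 1.56% of the RPKM total in the pericyte libraries against at least 2.25% in all others.

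In all, 3974 of 12748 genes passed, 2507 more positive and 1467 more negative. The median was 0.130, and median-ratio scaling, which moved it to -0.048, gave 50.3% of 3886 calls more positive in place of 63.1%. The count was 2633 and 2573 without CD146++ replicate 1 and 3, 2479 and 2532 without CD146- replicate 1 and 2, and 2095 without the fresh pericyte library, of which 1470 were among the 3974. Of the 31 named genes that passed, 23 stayed past the threshold whichever library was left out, and MCAM, PDGFRA and G0S2 were among those that did not.

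Adventitial cells with bright and dim aldehyde dehydrogenase activity were compared with culture state in the model. ALDH1A1, which encodes a main enzyme behind the Aldefluor signal, was at 174 RPKM in the bright and 69.4 in the dim fresh library and at 1.79 and 0.0804 in the cultured ones (log2 difference 1.34 ± 0.71, not passed). ALDH2 averaged 48.7 ± 31.6 RPKM in bright and 50.5 ± 33.3 in dim cells (SD, n = 2 each, -0.04 ± 0.51). Of 13 aldehyde dehydrogenase genes and 21 cytokine and chemokine genes, 0 passed, also adjusted over the list alone. The cytokine list passed camera with a median of 0.37 (adjusted p = 6.39e-05, adjusted p = 0.751 with an estimated correlation), with PTX3 at 0.61 ± 0.33 and NFKBIA at 0.19 ± 0.38; the aldehyde dehydrogenase list did not (adjusted p = 0.0979). With limma, 0 of 11914 genes passed, 24 had an unadjusted p under 0.05, and voom on approximate reads gave 0 as well, with 34 at an unadjusted p under 0.05. The 24 became 376 and 375 without the fresh and the cultured pericyte library, 371 with the 4 libraries sorted by activity alone, 60 and 78 without the cultured bright and dim library and 6 without the fresh bright one, with 0 passed in each. In simulated data of this design 0 of 66 genes changed by a log2 of 3 were recovered, so the count of 0 does not bear on smaller differences.

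The last questions were whether genes that separate primary pericytes from adventitial cells also separate the stem cell-derived fractions, and which primary cells those fractions resembled. Of 232 genes higher in pericytes that were tested in both, 38 rose in the CD146++ fraction and 8 fell, where independent lists would share 8.57 and 4.22. Of 499 genes lower in pericytes, 20 fell and 25 rose, where 9.07 and 18.4 would be shared. Genes shared as higher included MCAM, MYLK, MYL9 and CSPG4 (0.99 and 3.87 in stem cell-derived and primary cells). Fisher's exact test gave adjusted p = 2.18e-14 for the shared higher and 0.00164 for the shared lower genes, treating genes as independent, which they are not. As a set, the genes higher in pericytes had a median of 0.17 in the CD146++ fraction and did not pass camera (adjusted p = 0.111 over 2 sets, 0.502 with an estimated correlation), and the genes lower in pericytes had a median of 0.17 too (adjusted p = 0.194). Across 10174 genes, which are not independent replicates, the log2 differences had a Pearson r of -0.0577 and a Spearman rho of -0.173. Of the mural list, 12 of 21 genes tested in both were higher in both and 4 rose in both; of the adventitial list, 14 of 21 were lower in both and 0 fell in both.

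**Figure D4:**
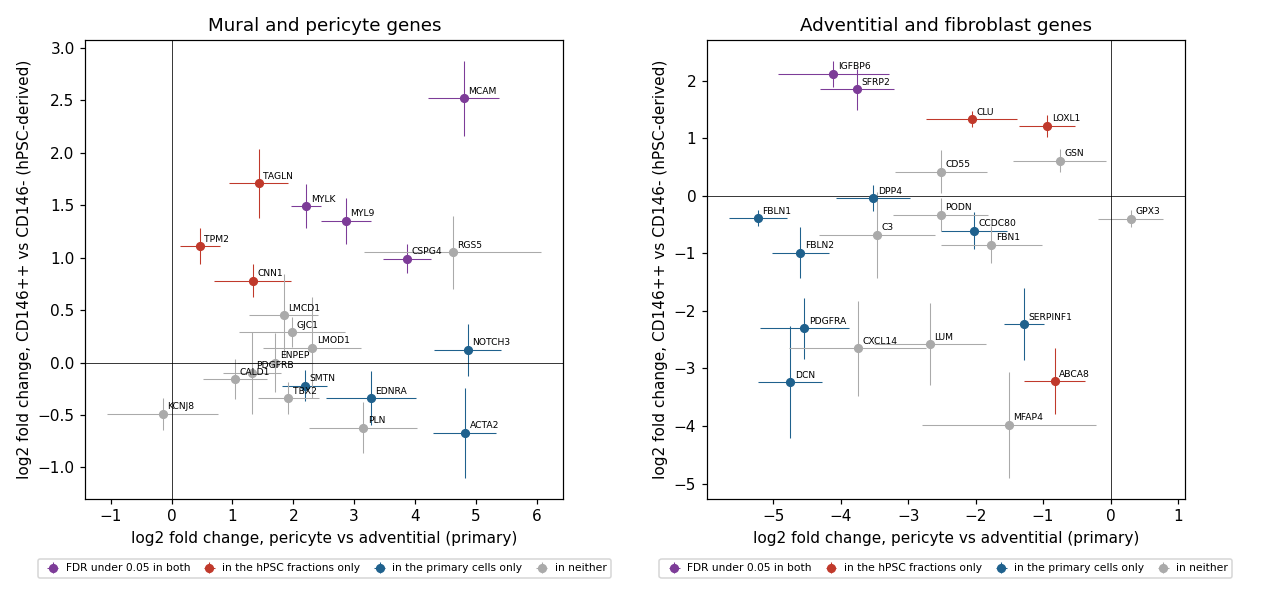
Each point is a gene of the mural (left) or adventitial (right) list, with its log2 difference ± SE between primary pericytes and adventitial cells on the x axis and between CD146++ and CD146- stem cell-derived cells on the y axis, coloured by where its adjusted p was under 0.05. MCAM lies at the upper right with 4.80 and 2.52, while ACTA2 lies at 4.82 and -0.67.

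By correlation of log2(RPKM + 1) across 12748 genes, all 6 stem cell-derived libraries were closest to a cultured adventitial library. The mean r with cultured adventitial cells was 0.823 ± 0.0132 (SD, n = 3) for the CD146++ and 0.772 ± 0.0268 for the CD146- libraries. With the cultured pericyte library it was 0.727 ± 0.00353 and 0.688 ± 0.00819. With the fresh pericyte library it was 0.513 ± 0.0238 and 0.543 ± 0.0267, and with fresh adventitial cells 0.588 ± 0.0241 and 0.616 ± 0.0197. Genes are not replicates, so no test was made of these values. Cultured pericytes were 1 library, with ribosomal protein transcripts at 1.56% of the RPKM total against 3.92% and 4.3% in cultured adventitial cells. Its estimated depth, 3470000 reads, was the lowest of the cultured primary libraries. It had 9725 genes at 1 RPKM or more, the fewest of any library. Whether these traits lower its r was not tested.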

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

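Each gene in this paragraph was singled out because the CD146 difference was not the same in the stem cell-derived and the primary cells, by the interaction test. The adjusted p values of that test hold no spread between pericyte libraries. NT5E, the gene of CD73, was higher in CD146++ cells (3.63) and lower in pericytes (-1.64), with an interaction of 5.21 (adjusted p = 0.000186). MCAM differed less in the stem cell-derived cells (2.52 against 4.80, interaction -2.20, adjusted p = 0.00696), as did PDGFRA (-2.30 against -4.54, interaction 2.14, adjusted p = 0.0318). Neither call held without the fresh pericyte library (MCAM -1.09, PDGFRA 1.09), and that of PDGFRA was lost without each of 5 other libraries too. With 1 pericyte library left out, the other was set against the mean of fresh and cultured adventitial cells, which mixes culture state with population. CD34, not tested in the stem cell-derived cells for its low values, had an interaction of 2.96 (adjusted p = 6.38e-05). S100A16 (2.81 and -3.67, interaction 6.61, adjusted p = 5.74e-06), STMN2 (3.77 and -2.68, interaction 6.61, adjusted p = 4.40e-05), G0S2 (5.24 and -1.03, interaction 6.47, adjusted p = 0.00373), THBD (3.00 and -3.07, interaction 6.18, adjusted p = 0.000203) and CD9 (2.86 and -2.67, interaction 5.55, adjusted p = 4.72e-05) had opposite signs, though the call of G0S2 was lost without the cultured pericyte library (2.84). The pericyte genes NDUFA4L2 (interaction -6.74, adjusted p = 7.89e-07), GPR116 (-6.17, adjusted p = 4.28e-06), HSPB7 (-5.14, adjusted p = 1.75e-05) and TINAGL1 (-5.00, adjusted p = 5.29e-07) were too low in the stem cell-derived cells to be tested there. ACTA2 was higher in pericytes (4.82) but not in CD146++ cells (-0.67), with an interaction of -5.56 (adjusted p = 0.000115). A gate on bright CD73 is given only for the CD146++ cells, and a gate on CD34 only for the primary cells. The interactions of NT5E and CD34 thus describe unlike gates at least in part. Source, culture and sort strategy differ together between the sides, so the values of the other genes do not say which of them matters.

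The tests of gene length, depth, label swap, sorting and blood cells below were chosen after the data were examined. Those of mitochondrial transcripts and of a mixture with CD146- cells were written before their values were computed. All intervals below, those of the HOX genes included, come from resampling genes, not libraries. Genes of a list are not independent, so these intervals do not measure spread between libraries or donors.

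Ribosomal protein transcripts were low in both pericyte libraries. Each was set against the median of other genes in its own of 20 bins of coding length. The median of these differences was -1.39 (95% interval over resampled genes -1.81 to -0.92). In these 2 libraries, the loss seen in other genes of like coding length thus could not account for the low ribosomal protein transcripts. The bins do not match the length of whole transcripts, so a loss of short transcripts is not excluded. Other genes of those bins, pooled, had a median of -0.31 too. A fresh adventitial library of like depth held at least 2.344 times the ribosomal share of the fresh pericyte library, so depth is not a likely cause. With mitochondrial genes left out, the pericyte shares were 1.479% and 1.837% against at least 3.047% elsewhere, so crowding by mitochondrial transcripts could not account for them. A difference between the populations, or in RNA quality, a loss of short transcripts included, stays open with 2 libraries.

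CD146++ replicate 2 lay between the fractions, and so did CD146- replicate 3, which had a higher r with it (0.9727) than with the other CD146- replicates (0.965 and 0.9643). If CD146++ replicate 2 held CD146- cells, the same share should serve all genes, whereas genes high in the other CD146++ replicates called for a share of 0.519 (0.467 to 0.615) and genes low in them for 0.302 (0.257 to 0.339), a difference of 0.217. That reckoning takes its CD146++ cells to have the profile of replicates 1 and 3, which was not measured and need not hold between replicates, so the unequal shares do not exclude a mixture and it stays open. A swap of labels is not likely, as the lowest CD146++ library had at least 3.353 times the MCAM and NT5E of the highest CD146- library. An earlier or slower state of the differentiation might give the same pattern, which was not tested.

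Immediate early and heat shock genes were high in the fresh libraries. Sorting alone could not account for this, since the median member was lower by 3.66 log2 units in the stem cell-derived libraries (-3.66, 95% interval -4.41 to -2.75) and by 3.93 in the cultured pericyte library (-3.93, -4.43 to -3.16), which were sorted too. Blood cells are not a likely source: each fresh library lay at least 2.53 above the cultured ones (1.58 to 3.87), while blood cell genes varied over 2.69 log2 units between fresh libraries and the immediate early genes over 1. Handling and digestion of the tissue may have induced these genes, as might their state in the body, and the data cannot part the 2.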

How the results depend on the processing

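Of 4270 values of 165 named genes under other settings, 3728 kept their direction and side of the threshold, 502 lost the call, 39 gained it and 1 reversed; 360 of those lost were lost by leaving out 1 library. ADIPOQ in the interaction was 1.39 without the fresh pericyte library, which held nearly all of its signal, and -9.26 without the cultured one. In each of these fits the remaining pericyte library was set against the mean of fresh and cultured adventitial cells. They thus mix culture state with population. Counts of genes past the threshold follow, with the cause not tested unless given. For CD146++ against CD146- cells the 659 became 439 with a log2 difference above 1 as well, 364 with no filter, 284 with at least 10 RPKM (fewer genes tested), 2242 with the replicate block and 13 to 1805 without 1 library. For pericytes against adventitial cells the 883 became 413 with no filter, 56 with no culture term, 4924 with all 13 libraries, 5964 with cultured libraries only, 298 with a pseudocount of 10, 1374 with voom and 172 to 2124 without 1 library. Culture gave 3553, then 1818 with at least 10 RPKM (fewer genes tested), 1935 with no population term and 1310 to 4252 without 1 library. CD146++ cells against pericytes gave 3583, then 2275 with at least 10 RPKM, 7424 with all 13 libraries, 5919 and 7264 with cultured and fresh pericytes only and 0 to 6847 without 1 library. CD146- against adventitial cells gave 3197, then 1538 with at least 10 RPKM, 6748 with all 13 libraries, 5596 and 6287 with cultured and fresh cells only and 1049 to 3655 without 1 library. The interaction gave 3974, then 2396 with at least 10 RPKM and 2095 to 5882 without 1 library. For aldehyde dehydrogenase activity the count stayed 0.

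Lists past the threshold of camera, in the order of the comparisons, were 9, 9, 15, 18, 14, 11 and 5. With an estimated correlation they were 0, 0, 0, 0, 0, 2 and 0, and with fry 3, 4, 9, 11, 9, 13 and 0, so nearly all list calls rest on the preset correlation. For the genes higher in pericytes, the unadjusted model-based value was 0.00904 with fry (adjusted p = 0.0181) and 0.00326 by camera with 200 genes from cultured libraries only, both with the genes higher in CD146++ cells. For the genes lower in pericytes it was 0.00158 from cultured libraries only, again higher in CD146++ cells (median 0.421), which is opposite to their direction in pericytes. From fresh libraries only the direction reversed (0.345). With an estimated correlation the values from cultured libraries were 0.207 and 0.455. With the replicate block the interaction gave 3859, and no call on the genes of pericytes changed. The similarity kept its order in every setting. DESeq2, edgeR with RLE factors and library-size scaling were not run, since they need counts and RPKM are already scaled to library size. Depth limits the fresh libraries most.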

Other observations

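HOX genes, which mark position along the body axis, differed between sources in single genes. HOXB9 averaged 8.91 and 6.32 RPKM in the CD146++ and CD146- cells and was at 0.105 RPKM or less in all primary libraries. HOXA13 and HOXB13, of the last paralogue group, were at 14.3 and 4.50 RPKM in the CD146- cells, but at 2.42 and 0.477 RPKM in the CD146++ cells. HOXA13 was at 2.81 RPKM in the fresh pericyte library. HOXC10, by contrast, averaged 15.3 and 21.3 RPKM in fresh and cultured adventitial cells and 0.265 and 0.643 RPKM in the stem cell-derived fractions, and HOXC6 averaged 14.7 RPKM in cultured adventitial cells against 2.15 and 2.65. The hypothesis, written before the test, was that posterior HOX genes are lower in both stem cell-derived fractions than in the primary cells. It was tested on the mean of the stem cell-derived libraries, and the fractions were not tested apart, though HOXA13 and HOXB13 differed between them. It was not borne out: the median log2 difference of 12 genes of paralogue groups 9 to 13 was 0.48 (95% interval -0.36 to 1.18), that of 12 genes of groups 1 to 5 was -0.57 (-0.86 to 0.08), and that of 7 genes of groups 6 to 8, for which no interval was computed, was -1.80.

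Of the 38 genes higher in CD146-positive cells of both sources, 7 chosen after their values were seen are given here, with no test of what the 38 share. IGFBP7 had log2 differences of 2.69 in the stem cell-derived and 4.04 in the primary cells, the integrin gene ITGA3 2.22 and 3.12, COL8A1 1.82 and 2.28, A2M 1.99 and 2.11, MYH9 1.15 and 1.67, ACTN1 1.04 and 1.41, and FLNA 0.82 and 1.28.

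Regrouping the same libraries asked how often a split calls as many genes as the real one. For CD146++ against CD146- cells it was 1 of 10 splits, the real one, with 659 genes, and no other split called a gene. Of these, 4 splits part all pairs of replicate numbers; with the pairs as a block the real one called 2242 genes and the others 0. With 10 splits, or 4, a share under 0.05 cannot be reached. For cultured against fresh cells it was 1 of 35, with at most 1619 genes in another split. For CD146- against adventitial cells it was 2 of 56, and the other split, which set the 3 fresh adventitial libraries apart, called 4292 genes. That split left the cultured adventitial libraries with the stem cell-derived ones, so it mixes culture state with source. Against cultured adventitial libraries only, 5596 genes passed, 2744 of them among the 3197. Against fresh ones only, 6287 passed, 3095 of them among the 3197. Most of the 3197 calls thus did not depend on which culture state of adventitial cells was used.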
